A study of Mus musculus with 11 samples.

How the data were processed

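Transcript levels were measured in 11 laser-captured samples of mouse prostate epithelium, primary prostate tumours and lung metastases on 2-colour Agilent oligonucleotide arrays. Per the labels, about 5000 cells were captured per sample, their RNA went through 2 rounds of amplification, and 825 ng of amplified RNA was labelled with Cy3. Each array also received a Cy5-labelled reference pool of normal tissue from Swiss-Webster males, made of 10% prostate and 30% each of testis, liver and kidney. The 4 groups were wild-type prostate epithelium (WT, 3 arrays, Cre-negative with floxed Pten), well-differentiated tumour (WD, 3 arrays), poorly differentiated tumour (PD, 2 arrays) and lung metastasis (MET, 3 arrays). None of the arrays used here was a dye swap.

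The deposited scanner files hold, per the file headers, spot and local background signals of both channels in units of intensity, and a dye-normalised ratio of reference over sample in log10. The submitters' processing notes name Agilent Feature Extraction, and the file headers give its version as 10.7.3.1. The deposited series matrix holds values in log2. Each of its columns was checked against the scanner files and equalled minus the scanner's log ratio on a log2 scale, so that it gives sample over reference, not centred on any gene: its column medians ran from 0.55 to 0.63. Of its 45180 values per array, 27.5% to 36.1% were empty, and these were the spots whose scanner p for the log ratio was above 0.05.

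All results came from the scanner signals unless another source is named. Mean signals were background-corrected against the median local background by the normexp method with an offset of 50, and the log2 ratio of sample to reference was normalised by loess within each array with control spots given no weight (limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8). The 45190 spots per array held 43765 non-control spots for 42204 probes, of which 1561 were spotted more than once and were averaged. Probes were kept if the sample channel was well above background, in the scanner's own call, on at least 2 arrays, which left 36113 probes. Probes were named from the accession in the file where a RefSeq gene table held it (23583 probes), then from the symbol or a synonym (9549 probes), then by the name in the file (1849 probes). A further 7223 probes had no name. Of the kept probes 30879 had a name, and the probe with the highest mean sample signal stood for each of 19430 genes. Probe positions are those in the files (mouse build mm8). No annotation for that build was at hand, so exons were not assigned.

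Groups were compared with limma (linear model on group over all 11 arrays, moderated by empirical Bayes, two-sided), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. There were 3 main comparisons (WD with WT, PD with WD, MET with WD) and 3 secondary ones (PD with WT, MET with WT, MET with PD). Changes are log2 ratios with the standard error (SE) of the model, and n is the number of arrays in the first and the second group. Where a probe was not well above background on any array of the dimmer group, its fold is given as a bound, written "at least", from the sample channel after loess and Aquantile normalisation with the dim group raised to the lowest signal called well above background on each array. The bounds describe the sample channel alone, so a bound can exceed the fold of the ratio where the reference channel moved too. The sample was in Cy3 on every array, so a dye bias equal on all arrays cancels in these bounds. Without dye swaps, a dye bias that differs between arrays was not checked. The number of arrays limits the precision, and the depth of an array has no count behind it.

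Gene lists were written before the data were examined, as were the comparisons, the test and the rule for named genes. The rule took Pten, Kras, Hmga2, Vim, Cdh1 and Ar in every comparison, the genes with the largest rises and falls whose groups did not overlap and whose brighter group was well above background on every array, and up to 4 members per list with the smallest p in the direction of the list's test, plus up to 2 significant members in the other direction. From these the text names those that showed most of each list. The 35 lists were: epithelial, mesenchymal, prostate secretory, androgen receptor targets, luminal epithelium, basal epithelium, neuroendocrine, stem and progenitor, proliferation, MAPK output, FOXO targets, histone deacetylases, chromatin regulators, TGF-beta response, NF-kB and chemokines, p53 and senescence, interferon response, MHC class I, MHC class II, hypoxia and glycolysis, sterol and fatty acid synthesis, oxidative phosphorylation, immediate early and heat shock, ribosomal proteins, lung epithelium, fibroblast, smooth muscle, endothelium, macrophage and neutrophil, lymphocyte, red blood cell, seminal vesicle, reference testis, reference liver and reference kidney. Each was tested with camera (limma) over the 19270 genes with a value on every array at a preset inter-gene correlation of 0.01, adjusted over the 35 lists of a comparison, and again with an estimated correlation. A further 160 genes lacked a value on at least 1 array. With an estimated correlation, list calls remained in PD against WT for the macrophage and neutrophil list and the TGF-beta response list (adjusted p = 0.0396 each) and in none of the other 5 comparisons.

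The alternatives were Agilent's processed signals, no background correction, Aquantile normalisation between arrays, the sample channel alone, no filter on dim probes, a filter on both channels on all arrays, the series matrix values, slide as a random block, the replicate number as a block, the 2 compared groups alone, empirical Bayes with trend and robust options, array weights, the mean of all probes of a gene, camera with an estimated correlation, slide as a fixed block among the tumours, the arrays within slide 3 alone, and leaving out each array. A fit to the arrays within slide 4 alone was added after the data were examined. The tests were checked on simulated data with the arrays' own spread, 19270 genes of which 200 were given a change, 50 at each of 4 sizes. Noise was drawn independently for each gene, and far fewer genes changed than the 22.0% to 46.3% called in the real comparisons. The simulated rates therefore do not carry over to the real comparisons, and correlated genes were not simulated. A log2 change of 1 was called in 18% of genes for WD against WT, 16% for PD against WD and 26% for MET against WD, and a log2 change of 2 in 72%, 72% and 74%. In these 3 simulations 8 of 149, 9 of 139 and 13 of 155 calls were false. For PD against WT, MET against WT and MET against PD a change of 2 was called in 74%, 72% and 58% of genes, with 7 of 144, 7 of 150 and 16 of 140 calls false.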

Results

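The series compared laser-captured regions of mouse prostate and lung, chosen by their histopathology, on 11 arrays: wild-type prostate epithelium (WT, n = 3), well-differentiated primary tumour (WD, n = 3), poorly differentiated primary tumour (PD, n = 2) and lung metastasis (MET, n = 3). The tumours came from mice with Cre recombinase under the probasin promoter, floxed Pten and an activated Kras allele. The sample labels give the tumours 1 floxed Pten allele, whereas the series design gives both alleles as floxed. The labels call the arrays biological replicates but do not tie regions to animals, so tumours and metastases may share animals, and p-values over regions may then be too small. The sample channel was well above background for 65.3% (PD 2) to 83.3% (WT 3) of probes, and no spot was saturated. Spots with uneven signal numbered 165 on MET 1, 85 on PD 1 and at most 16 on each of the other arrays. The WT arrays sat on slides 1 and 2 and were scanned in another batch than the tumours on slides 3 and 4, so slide, scan batch and genotype cannot be told apart in comparisons with WT. All fold changes are log2 values ± SE from limma.

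Pten, the phosphatase that opposes PI3 kinase, and Kras, the GTPase carried in an activated form, were read first in every sample. The brightest of 5 Pten probes (chromosome 19, 32884017 to 32885858, mm8) read log2 sample over reference of 0.05 ± 0.09 (SD, n = 3) in WT, -0.20 ± 0.39 (SD, n = 3) in WD, 0.07 ± 0.26 (SD, n = 2) in PD and -0.38 ± 0.20 (SD, n = 3) in MET. Pten was -0.25 ± 0.23 in WD against WT (adjusted p = 0.413), and 2 of its 5 probes shared that sign. It was 0.27 ± 0.26 in PD against WD (adjusted p = 0.512), -0.18 ± 0.23 in MET against WD (adjusted p = 0.65) and -0.43 ± 0.23 in MET against WT (adjusted p = 0.148), where the mean of its probes was 0.57. In PD against WD and in MET against WD every other Pten probe had the opposite sign to this brightest one. The labels do not state which part of Pten is deleted, and a probe outside it does not test the deletion. Kras (chromosome 6, 145174252 to 145174311) read 0.42 ± 0.14 (SD, n = 3) in WT, 1.58 ± 0.38 (SD, n = 3) in WD, 0.58 ± 0.06 (SD, n = 2) in PD and 2.06 ± 0.04 (SD, n = 3) in MET. It rose by 1.17 ± 0.21 in WD against WT (adjusted p = 0.00182) with the same sign in 4 of 4 probes. In PD against WD Kras fell by 1.00 ± 0.23 (adjusted p = 0.0106). This call was lost without PD 1 (-1.04, adjusted p = 0.0516), without PD 2 (-0.96, adjusted p = 0.0706), with slide as a fixed block (-0.76, adjusted p = 0.0837) and within slide 4 (-0.57, adjusted p = 0.286). In MET against WD Kras was 0.48 ± 0.21 (adjusted p = 0.138), with the same sign in 2 of 4 probes. These readings measure total Kras transcript and do not distinguish the mutant allele. Hmga2, a chromatin architecture gene, was -0.43 ± 0.28 in WD against WT (adjusted p = 0.245), 0.47 ± 0.31 in PD against WD (adjusted p = 0.323) and -0.05 ± 0.28 in MET against WD (adjusted p = 0.922).

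**Figure D1:**
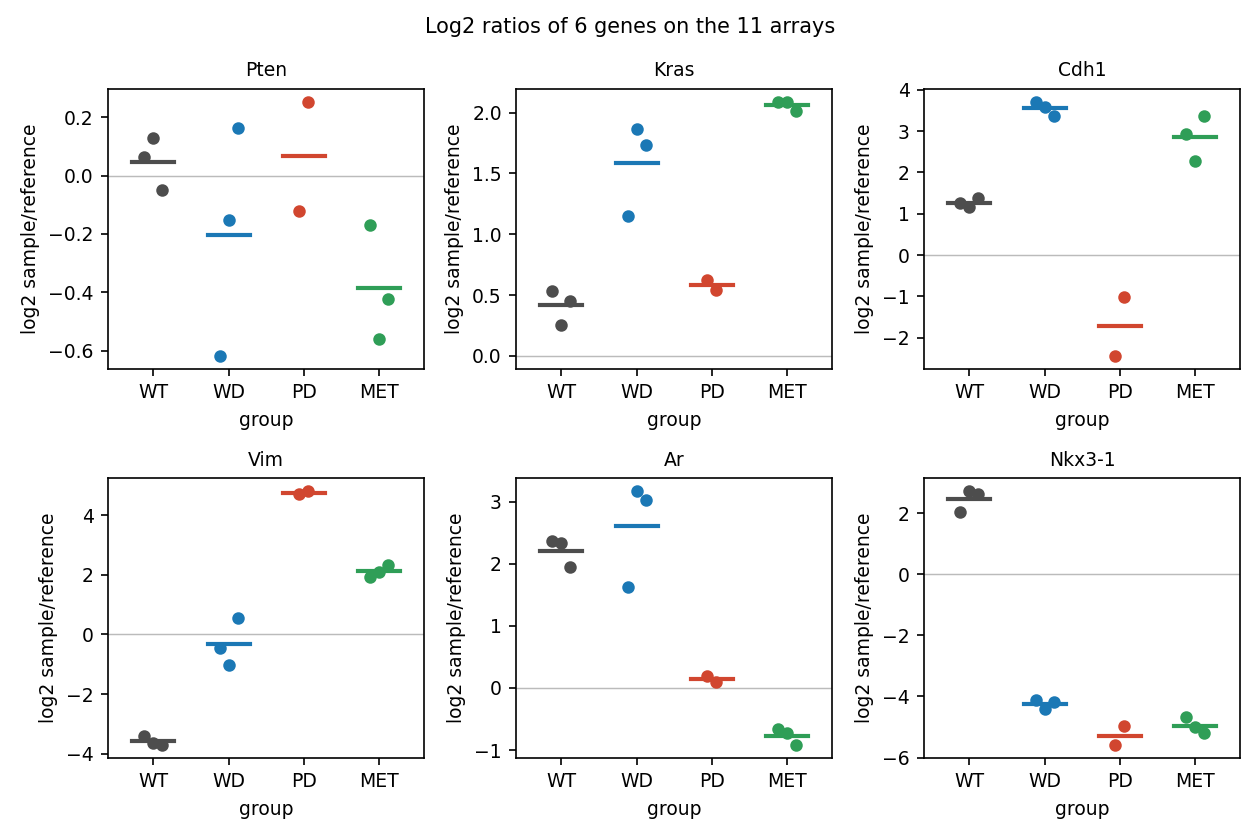
Log2 ratio of sample to reference for 6 genes on each array (points) with group means (lines), for WT, WD, PD and MET. Vim lay at -3.59 on average in WT and 4.76 in PD, while Cdh1 lay at 3.55 in WD and -1.72 in PD.

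The first comparison, WD with WT, asked how well-differentiated tumour differed from normal prostate epithelium. Secreted products of the normal prostate were lower: Pbsn, which encodes probasin, fell by 8.99 ± 0.33, Tgm4, the prostate transglutaminase, by 8.36 ± 0.45, and Azgp1, a secreted glycoprotein, by 5.18 ± 0.46 (n = 3 and 3 for these and the following genes). Nkx3-1, the prostate homeobox gene, fell by 6.70 ± 0.26 and Fcgbp, a mucus-associated protein, fell by 7.36 ± 0.26. Cxcl5, a neutrophil-attracting chemokine, was at least 683-fold higher by the sample channel, and Il1rn, the interleukin 1 receptor antagonist, at least 254-fold. Ltf, lactoferrin, rose by 8.07 ± 1.04. Spp1, the secreted matrix protein osteopontin, rose by 6.98 ± 1.02. Cdh1 (E-cadherin) rose by 2.28 ± 0.37 and so did the intermediate filament gene Vim, by 3.28 ± 0.34, while Ar, the androgen receptor, was 0.39 ± 0.36 (adjusted p = 0.409). Without WD 1, Ar was 0.88 with an adjusted p of 0.00566.

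In the prostate secretory list 7 of 11 genes fell, 2 rose and 2 did not pass, with the same numbers adjusted over the list alone (median -2.89, camera adjusted p = 0.00381; adjusted p = 0.128 with an estimated correlation). The median was -4.67 without WD 2, and the members that rose included Msmb, a secreted microseminoprotein, at 2.58 ± 0.63. Proliferation genes rose: 21 of 33 were higher and 2 lower, 22 and 2 adjusted over the list alone (median 1.00, adjusted p = 5.57e-07; adjusted p = 0.134 with an estimated correlation). Of the DNA replication factors, Mcm3 rose by 2.47 ± 0.26 and Mcm6 by 1.81 ± 0.19. Of 25 genes of MAPK output, 15 rose and 1 fell, 16 and 1 adjusted over the list alone (median 1.98, adjusted p = 9.41e-07; adjusted p = 0.241 with an estimated correlation). The MAPK output list mean against WT was 1.047 in WD 1, against 2.52 in WD 2 and 2.291 in WD 3. The ERK phosphatase Dusp4 rose by 4.24 ± 0.30, Dusp6, another, by 3.43 ± 0.37 and the receptor Epha2 by 3.40 ± 0.24. Immediate early and heat shock genes, a list kept as a sign of RNA or tissue handling, rose beside them in 7 of 13 cases and fell in none, 8 and none adjusted over the list alone (median 1.32, adjusted p = 0.000544; adjusted p = 0.241 with an estimated correlation). The transcription factor Egr1 rose by 3.89 ± 0.81 and Fos, another, by 4.39 ± 0.74, and the median was 0.58 with all probes of a gene averaged. In the NF-kB and chemokine list 13 of 20 genes rose and none fell, also when adjusted over the list alone (median 1.69, adjusted p = 3.46e-05; adjusted p = 0.134 with an estimated correlation). The monocyte chemokine Ccl2 rose by 4.11 ± 0.51 and Tnfaip3, a feedback inhibitor of NF-kB, by 1.71 ± 0.27. The macrophage and neutrophil list moved with it: 14 of 21 genes rose and none fell, the same adjusted over the list alone (median 2.26, adjusted p = 2.94e-07; adjusted p = 0.128 with an estimated correlation). Lyz2, a lysozyme gene, rose by 5.78 ± 0.55 and Mrc1, the macrophage mannose receptor, by 4.18 ± 0.36. Medians that moved by more than 1.5 times without losing the call were proliferation (1.70) and NF-kB and chemokines (2.68) with Agilent's processed signals, NF-kB and chemokines with the series matrix values (2.66), prostate secretory with both channels above background (-5.18) and macrophage and neutrophil with array weights (1.45).

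Cell cycle inhibitors were among the 8 of 14 genes of the p53 and senescence list that rose (1 fell, both numbers the same adjusted over the list alone): Cdkn2b by 5.44 ± 0.39 and Cdkn2a by 2.93 ± 0.41 (median 1.19, adjusted p = 0.00294; adjusted p = 0.128 with an estimated correlation). In the TGF-beta response list 8 of 16 genes rose and 1 fell, 9 and 2 adjusted over the list alone (median 1.64, adjusted p = 0.000984; adjusted p = 0.128 with an estimated correlation). With both channels required to be well above background on all arrays, the TGF-beta response median was 0.25 and the call was lost (adjusted p = 0.0586), and it was 2.57 in the series matrix values and 0.91 with all probes of a gene averaged. The type II receptor Tgfbr2 rose by 3.77 ± 0.18 and the matrix protein Ccn2 by 4.21 ± 0.50. Hypoxia and glycolysis genes rose in 10 of 21 cases and fell in none, 11 and none adjusted over the list alone (median 0.89, adjusted p = 0.00018; adjusted p = 0.241 with an estimated correlation). The hexokinase Hk2 rose by 4.29 ± 0.21 and the oxygen sensor Egln3 by 5.34 ± 0.35. Of the stem and progenitor list 5 of 16 rose and none fell, also over the list alone (median 0.98, adjusted p = 0.00283; adjusted p = 0.134 with an estimated correlation). Of the surface antigens, Ly6a rose by 5.24 ± 0.42 and Tacstd2 by 3.90 ± 0.32. Interferon response genes were higher in 11 of 20 cases, 12 adjusted over the list alone, and lower in none (median 2.37, adjusted p = 0.000144; adjusted p = 0.681 with an estimated correlation). The antiviral synthetase Oas2 rose by 5.53 ± 0.65. The interferon median was 1.38 with array weights and 1.34 without WD 1, whose interferon list mean against WT was 4.37, against 0.94 in WD 2 and 1.40 in WD 3.

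The lists behind the epithelial and mesenchymal states that the series title names did not pass in WD against WT. Of 30 epithelial genes 8 rose and 4 fell (median 0.29, adjusted p = 0.0711), and of 32 mesenchymal genes 5 rose, among them the protease inhibitor Serpine1 (5.55 ± 0.36), and 6 fell, among them the transcription factor Twist2 (-3.96 ± 0.49) (median 0.13, adjusted p = 0.273). The counts adjusted over the list alone were the same for both lists. The epithelial list passed without WD 1 (0.32, adjusted p = 0.0491), PD 1 (0.29, adjusted p = 0.0286) or PD 2 (0.29, adjusted p = 0.0282), and the mesenchymal median was -0.06 without WD 1. Of 18 fibroblast markers 7 fell, among them the receptor Pdgfra (-3.15 ± 0.46), and 1 rose, 10 and 2 adjusted over the list alone (median -1.01, adjusted p = 0.0711), and the list passed without WD 1 (-1.34, adjusted p = 0.00175). Histone deacetylases, named in the series title, fell in 6 of 18 cases, including Hdac11 (-1.66 ± 0.21) and Hdac10 (-1.31 ± 0.25), and rose in 3, 7 and 4 adjusted over the list alone (median -0.46, adjusted p = 0.24).

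In all, 7775 of 19430 genes (40.0%) differed between WD and WT, 3219 higher and 4556 lower, and 6681 did with slide as a random block. The median of all genes was -0.17 in this comparison, -0.21 in PD against WT and -0.21 in MET against WT, so directions close to these values are relative to that shift. The reference channel, which carried 1 pool on every array, differed between WD and WT by more than 1 log2 unit for 302 genes, in 294 of them in the direction of the sample channel. For those 294 genes, Cdh1 among them, the ratio gives less of a change in that direction than the sample channel, and for the other 8 more. Tgm4 is of the second kind: its sample signal was 19.15 in WT and 11.97 in WD (n = 3 each), and its reference signal 16.46 and 17.64. In the dimmer group the probe was well above background on 1 of 3 arrays for Fcgbp, Cdkn2a and Serpine1 and on 2 of 3 for Mrc1, Oas2, Pdgfra and Twist2. With the genes known by a bound alone set to that bound, the largest move of any list median was 0.45 and none changed sign.

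**Figure D2:**
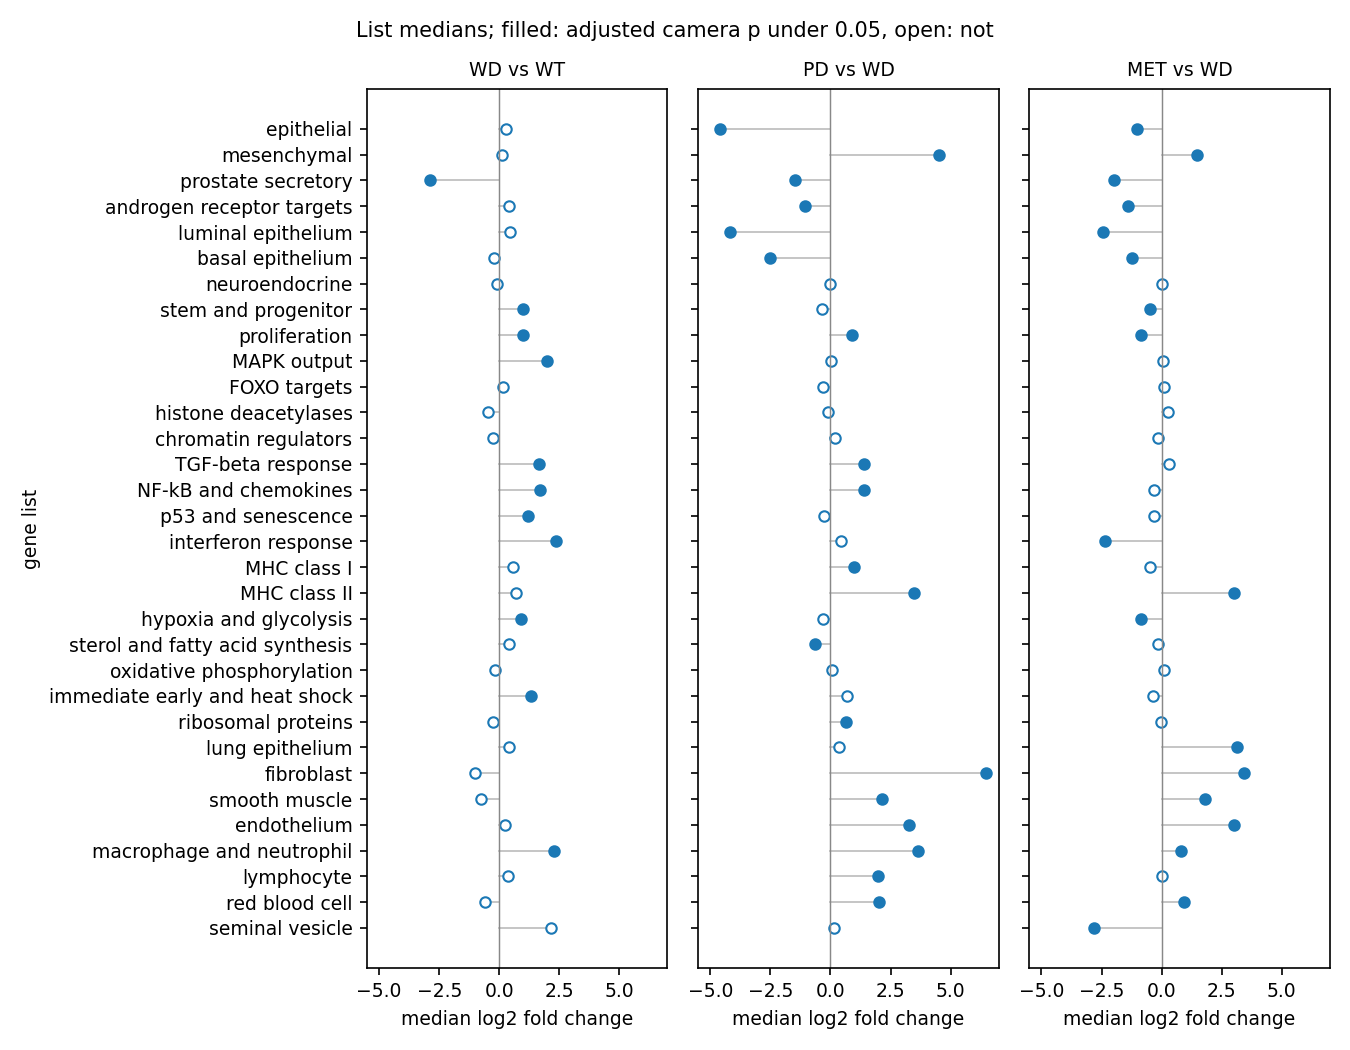
Median log2 fold change of 32 gene lists (dots) in WD against WT, PD against WD and MET against WD. Filled dots passed camera at an adjusted p under 0.05 with the preset correlation and open dots did not, and the fibroblast list reached 6.46 in PD against WD.

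The second comparison, PD with WD, set poorly against well-differentiated primary tumour and bears on the epithelial and mesenchymal states named in the series title. Epithelial genes fell: Cdh1 by 5.27 ± 0.41, the keratin Krt18 by 5.17 ± 0.29, the desmosome gene Dsp by 5.45 ± 0.32 and the splicing factor Esrp2 by 3.99 ± 0.25 (n = 2 and 3 for these and the following genes). Vim rose by 5.07 ± 0.38 and the transcriptional repressor of E-cadherin Snai1 by 5.02 ± 0.28, and Lox, a collagen crosslinking enzyme, was at least 53.8-fold higher by the sample channel. The largest rises included the collagens Col3a1 (9.03 ± 0.52) and Col1a2 (9.02 ± 0.50), the protease inhibitor Serpinb2 (8.87 ± 0.25), the proteoglycan Lum (8.62 ± 0.82) and Pdgfra (8.54 ± 0.51). The largest falls included the matrix protease Mmp7 (-7.70 ± 0.65), the tetraspanin Tspan8 (-7.74 ± 0.80), the desmosome-associated gene Perp (-7.22 ± 0.50) and Lypd8, an epithelial surface protein (-8.15 ± 1.02). Ar fell by 2.46 ± 0.40 and its target Tmprss2, a membrane protease, fell by 6.55 ± 0.52.

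Of 30 epithelial genes 29 fell and 1 rose, the same adjusted over the list alone (median -4.58, adjusted p = 1.45e-25; adjusted p = 0.0548 with an estimated correlation). The gene that rose, Cdh3 (P-cadherin, 3.47 ± 0.65), lost its call with the 2 groups alone (adjusted p = 0.0513) and in the series matrix values (adjusted p = 0.134). Of 32 mesenchymal genes 27 rose and none fell, 28 and none adjusted over the list alone (median 4.53, adjusted p = 9.32e-20; adjusted p = 0.0548 with an estimated correlation). Markers of other cell types rose with them. In the fibroblast list 17 of 18 genes rose, also over the list alone (median 6.46, adjusted p = 2.26e-16; adjusted p = 0.12 with an estimated correlation). Col6a1, a collagen, rose by 6.28 ± 0.28. In the macrophage and neutrophil list 18 of 21 rose, also over the list alone (median 3.65, adjusted p = 3.11e-11; adjusted p = 0.0548 with an estimated correlation). The complement gene C1qb rose by 4.36 ± 0.28 and the macrophage receptor Adgre1 by 4.92 ± 0.43. Endothelial genes rose in 12 of 14 cases, 13 adjusted over the list alone (median 3.26, adjusted p = 1.35e-09; adjusted p = 0.128 with an estimated correlation). The tight junction gene Cldn5 rose by 3.32 ± 0.23. Smooth muscle genes rose in 7 of 11 cases, also over the list alone (median 2.13, adjusted p = 4.35e-05; adjusted p = 0.195 with an estimated correlation). Tagln, an actin-binding protein, rose by 4.61 ± 0.36. Lymphocyte genes rose in 10 of 20 cases, among them the B cell receptor component Cd79b at 3.98 ± 0.20, against 14 rises and 1 fall adjusted over the list alone (median 1.96, adjusted p = 9.43e-06; adjusted p = 0.271 with an estimated correlation). No gene of these 5 lists fell over all genes tested, and 1 mesenchymal gene is also on the smooth muscle list. Of 13 immediate early and heat shock genes, a list kept as a sign of handling, 4 rose and 1 fell, also over the list alone (median 0.70, adjusted p = 0.0517). That list passed with slide as a fixed block (0.84, adjusted p = 0.035), without WD 2 (0.79, adjusted p = 0.0271) and without WD 3 (0.72, adjusted p = 0.0172). Its median was 1.26 within slide 4. Ribosomal proteins, the other list kept as a sign of handling, passed upward (median 0.63, adjusted p = 0.000108, and 0.293 with an estimated correlation).

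Luminal epithelial genes fell in 12 of 14 cases and rose in 1, the same over the list alone (median -4.16, adjusted p = 2.35e-09; adjusted p = 0.0916 with an estimated correlation). Krt8 fell by 4.30 ± 0.31 and Tacstd2 by 4.75 ± 0.35. Secretory genes fell in 5 of 11 cases, 6 over the list alone (median -1.48, adjusted p = 0.00388; adjusted p = 0.0916 with an estimated correlation). Proliferation genes rose in 15 of 33 cases and fell in 1, 17 and 1 adjusted over the list alone (median 0.90, adjusted p = 2.85e-06; adjusted p = 0.128 with an estimated correlation). Mcm3 rose by 1.96 ± 0.29 and the spindle checkpoint kinase Bub1b by 1.97 ± 0.29. MHC class II genes, which present antigen, rose in 6 of 7 cases, 7 over the list alone (median 3.49, adjusted p = 8.57e-06; adjusted p = 0.128 with an estimated correlation). Cd74 rose by 3.77 ± 0.33 and H2-Ab1 by 3.61 ± 0.39. TGF-beta response genes rose in 7 of 16 cases, also over the list alone (median 1.40, adjusted p = 0.00121; adjusted p = 0.0607 with an estimated correlation). The matrix protein Tgfbi rose by 4.73 ± 0.51 and the ligand Tgfb1 by 2.41 ± 0.29, and the median was 0.78 with all probes of a gene averaged. Histone deacetylases rose in 2 of 18 cases and fell in 2, 2 and 3 adjusted over the list alone (median -0.09, mean 0.03, adjusted p = 0.616).

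In WD the probe was well above background on 1 of 3 arrays for Serpinb2 and on 2 of 3 for Lum, Pdgfra and Snai1. Between PD and WD 4778 genes (24.6%) differed, 2602 higher and 2176 lower. The count was 3070 without PD 1 and 3056 without PD 2. With slide as a fixed block among the tumours it was 4060, and within slide 4, with 1 WD array taken to vary like the PD pair, 4012. The epithelial median was -4.54 with that block and -4.35 within slide 4, the mesenchymal median 3.95 and 3.80, the fibroblast median 6.21 and 5.59, and the macrophage and neutrophil median 3.58 and 3.33. The lymphocyte median was 0.91 with the block and 0.59 within slide 4, and the prostate secretory median -0.98 with the block. Of the 19 lists called, 15 kept the call with the block and 15 within slide 4. The exceptions in both fits were MHC class I, NF-kB and chemokines, androgen receptor targets, and sterol and fatty acid synthesis.

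**Figure D3:**
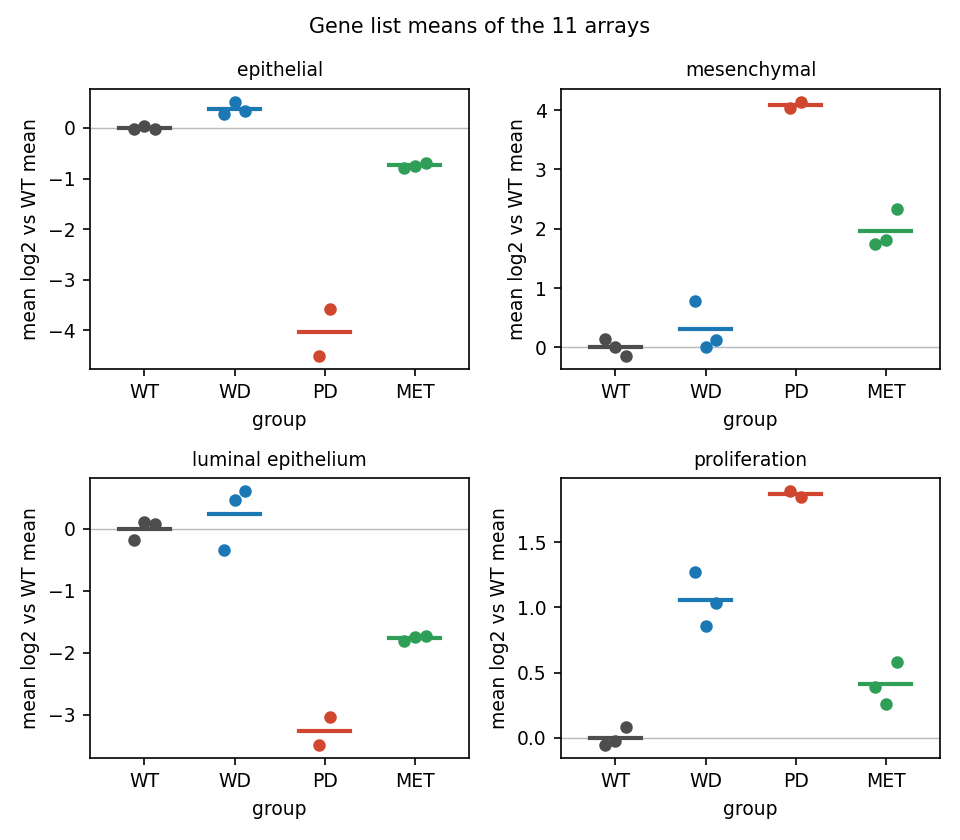
Mean over list genes of the log2 ratio relative to the WT mean, for each array (points) with group means (lines). The PD arrays lay at -4.50 and -3.57 for the epithelial list and at 4.03 and 4.14 for the mesenchymal list, while the MET arrays lay between -0.78 and -0.68 and between 1.74 and 2.33.

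The third comparison, MET with WD, set lung metastasis against well-differentiated primary tumour. The metastases carried lung transcripts: Napsa, an aspartic protease of alveolar type II cells, rose by 5.77 ± 0.33 and Rtkn2, a type I cell gene, by 5.26 ± 0.34 (n = 3 and 3 for these and the following genes). Ager, a receptor abundant in type I cells, was at least 60.3-fold higher by the sample channel. The surfactant gene Sftpc had a sample signal of 19.83 ± 0.38 on the log2 scale in MET (SD, n = 3), against 11.45 ± 2.49 in WD (SD, n = 3), and Sftpa1, another, 19.70 ± 0.12 (SD, n = 3) against 8.86 ± 2.06 (SD, n = 3). These genes, picked after their values were seen, showed smaller ratios (0.72 ± 0.79 for Sftpc, adjusted p = 0.594, and 1.79 without WD 1, adjusted p = 0.015) because their reference channel read high on the MET arrays too, 15.80 ± 0.81 (SD, n = 3) for Sftpc against 8.13 ± 0.65 in WD (SD, n = 3). The largest rises included the membrane protein gene Mlc1 (8.56 ± 0.38), Retnla, a resistin-like secreted protein (8.25 ± 0.38), Irx1, a homeobox gene (8.10 ± 0.53), Cd36, a fatty acid receptor (8.05 ± 0.45) and Lrp2, an endocytic receptor (7.72 ± 0.21). The largest falls included Mmp7 (-8.76 ± 0.58), the pleckstrin homology gene Plekhs1 (-8.28 ± 0.49) and Sox9, a transcription factor of progenitor cells (-7.82 ± 0.39). By the sample channel Onecut2, a transcription factor, was at least 292-fold lower, Hoxb13, a prostate homeobox gene, at least 47.5-fold lower and Ar at least 7.21-fold lower.

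Lung epithelium genes rose in 12 of 20 cases and fell in none, 15 and none adjusted over the list alone (median 3.16, adjusted p = 1.69e-11; adjusted p = 0.191 with an estimated correlation), and from the sample channel alone the median was 6.16. Beside them, endothelial genes rose in 13 of 14 cases, 14 over the list alone (median 3.02, adjusted p = 3.02e-11; adjusted p = 0.191 with an estimated correlation). The VEGF receptor Flt1 rose by 4.18 ± 0.37. Fibroblast genes rose in 13 of 18 cases, 14 over the list alone (median 3.42, adjusted p = 2.39e-10; adjusted p = 0.213 with an estimated correlation). The proteoglycan Bgn rose by 3.36 ± 0.20. Mesenchymal genes rose in 18 of 32 cases and fell in none, 19 and none adjusted over the list alone (median 1.46, adjusted p = 7.2e-08; adjusted p = 0.2 with an estimated correlation). Snai1 rose by 3.89 ± 0.25, the matrix protein Postn by 5.05 ± 0.39 and Vim by 2.43 ± 0.34. Epithelial genes fell in 15 of 30 cases and rose in 1, the same over the list alone, with Krt18 at -1.91 ± 0.26 and Cdh1 at -0.70 ± 0.37 (adjusted p = 0.223) (median -1.04, adjusted p = 1.17e-05; adjusted p = 0.271 with an estimated correlation). Macrophage and neutrophil genes rose in 5 of 21 cases, 6 over the list alone, and fell in none (median 0.79, adjusted p = 0.034; adjusted p = 0.436 with an estimated correlation). That call was lost without WD 2 (0.22, adjusted p = 0.156), without MET 2 (0.62, adjusted p = 0.119) and within slide 4 (0.21, adjusted p = 0.23), and the median was 1.22 with array weights. MHC class II genes rose in 7 of 7 cases, also over the list alone (median 3.03, adjusted p = 1.41e-06; adjusted p = 0.191 with an estimated correlation). Cd74 rose by 3.64 ± 0.29.

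Luminal epithelial genes fell in 10 of 14 cases and rose in 1, 11 and 1 over the list alone (median -2.43, adjusted p = 1.34e-05; adjusted p = 0.213 with an estimated correlation). The luminal median was -1.33 with both channels required to be above background on all arrays. The stem cell antigen Prom1 fell by 4.91 ± 0.45. Androgen receptor targets fell in 10 of 19 cases and rose in 1, 13 and 2 over the list alone (median -1.38, adjusted p = 0.000198; adjusted p = 0.191 with an estimated correlation). The transporter Slc45a3 fell by 3.86 ± 0.28. Proliferation genes fell in 14 of 33 cases and rose in 1, 21 and 2 over the list alone (median -0.86, adjusted p = 9.9e-05; adjusted p = 0.213 with an estimated correlation). The helicase gene Mcm2 fell by 1.16 ± 0.17 and the cyclin Ccna2 by 1.14 ± 0.19. Hypoxia and glycolysis genes fell in 8 of 21 cases and rose in 2, 9 and 2 over the list alone (median -0.85, adjusted p = 0.00171; adjusted p = 0.291 with an estimated correlation). Egln3 fell by 6.27 ± 0.35 and the glycolytic kinase Pgk1 by 2.69 ± 0.30. Interferon response genes fell in 7 of 20 cases, 10 over the list alone, with Oas2 at -4.61 ± 0.65 (median -2.34, adjusted p = 0.00026; adjusted p = 0.633 with an estimated correlation), and the median was -0.92 without WD 1, -1.04 within slide 3 and -0.76 with array weights, where the call was lost (adjusted p = 0.0609). Histone deacetylases rose in 2 of 18 cases and fell in 3, also over the list alone (median 0.27, adjusted p = 0.685).

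In the dimmer group the probe was well above background on 1 of 3 arrays for Mlc1 and on 2 of 3 for Rtkn2, Snai1, Sox9 and Egln3. Between MET and WD 4284 genes (22.0%) differed, 2275 higher and 2009 lower, 4556 with slide as a fixed block, 4253 within slide 3 and 1816 within slide 4. Slide 4 holds 1 array of each of the 2 groups, so the spread there came from its 2 PD arrays and the single arrays were taken to vary like them. The lung median was 3.16 with the block, 3.49 within slide 3 and 3.14 within slide 4. For the epithelial list these medians were -1.04, -1.27 and -0.96, for the mesenchymal list 1.46, 1.63 and 1.19, and for the fibroblast list 3.42, 3.76 and 2.61. Of the 18 lists called, 17, 16 and 14 kept the call in these 3 fits, and the exceptions were seminal vesicle, red blood cell, macrophage and neutrophil, smooth muscle, and stem and progenitor. Krt18 (-1.40, adjusted p = 0.196), Mcm2 (-0.94, adjusted p = 0.226) and Ccna2 (-1.27, adjusted p = 0.115) lost their calls within slide 4, where the MHC class II median was 1.60, the luminal epithelium median -1.50 and the interferon response median -3.94.

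**Figure D4:**
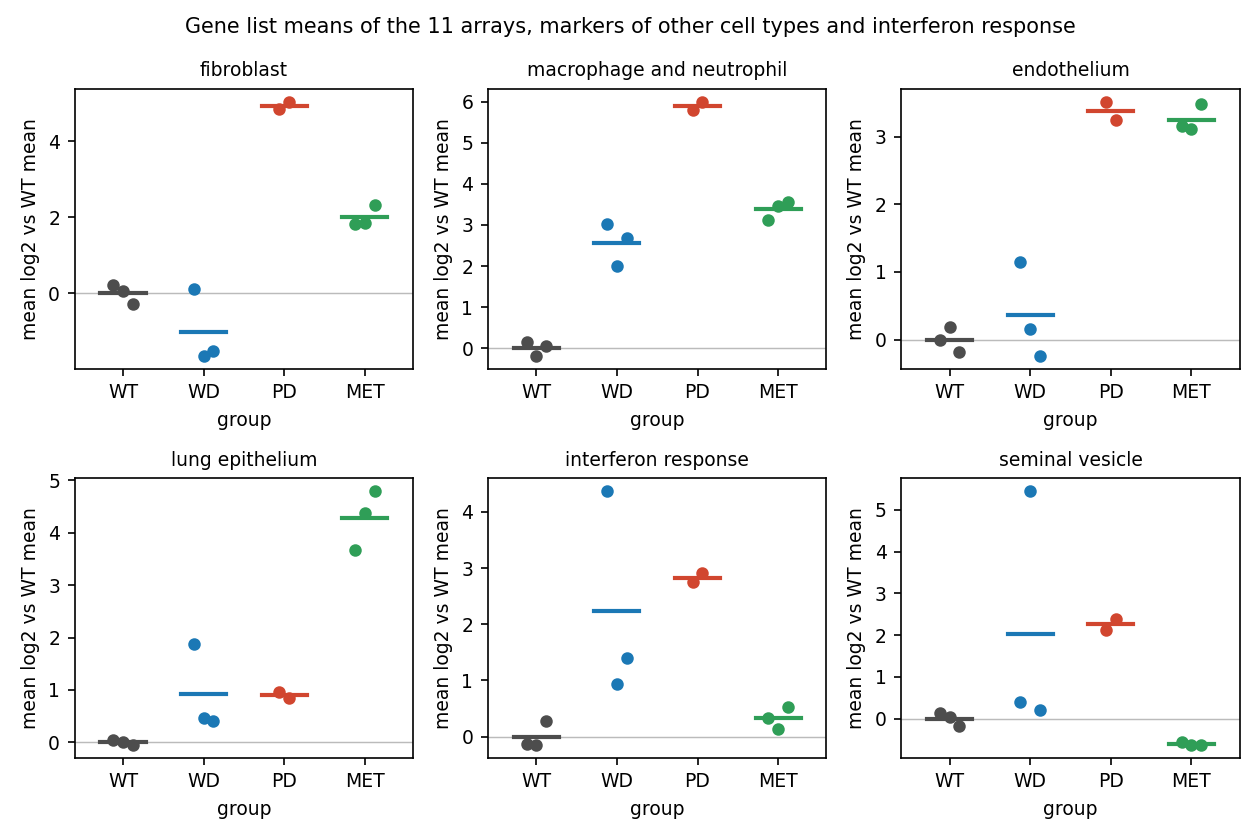
Mean over list genes of the log2 ratio relative to the WT mean, for each array (points) with group means (lines). The MET arrays lay between 3.67 and 4.80 for the lung epithelium list, WD 1 at 4.37 for the interferon response list and WD 2 at 5.46 for the seminal vesicle list.

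MET and PD were also compared directly. Cdh1 was higher in MET by 4.57 ± 0.41, the tight junction gene Cldn3 by 5.50 ± 0.39 and Esrp2 by 4.29 ± 0.25, while Vim was lower by 2.64 ± 0.38 and Cdh2, N-cadherin, by 5.04 ± 0.44 (n = 3 and 2). Of 30 epithelial genes 28 were higher and 1 lower, the same over the list alone (median 3.54, adjusted p = 5.25e-20; adjusted p = 0.116 with an estimated correlation). Of 32 mesenchymal genes 19 were lower and 1 higher, 23 and 1 adjusted over the list alone (median -2.03, adjusted p = 4.4e-10; adjusted p = 0.141 with an estimated correlation). Lung epithelium genes were higher beside the epithelial list, in 14 of 20 cases and lower in none, also over the list alone (median 3.40, adjusted p = 3.04e-10; adjusted p = 0.141 with an estimated correlation). Fibroblast genes moved with the mesenchymal list, 14 of 18 lower, also over the list alone (median -2.80, adjusted p = 1.13e-07; adjusted p = 0.39 with an estimated correlation). So did macrophage and neutrophil genes, 15 of 21 lower, 16 over the list alone (median -2.87, adjusted p = 6.03e-08; adjusted p = 0.138 with an estimated correlation). Lymphocyte genes were lower in 10 of 20 cases, 14 over the list alone (median -1.94, adjusted p = 0.00039; adjusted p = 0.39 with an estimated correlation), and smooth muscle genes in 5 of 11, 6 over the list alone (median -2.02, adjusted p = 0.00544; adjusted p = 0.39 with an estimated correlation). Proliferation genes were lower in 24 of 33 cases, 29 over the list alone, with Ccna2 at -2.28 ± 0.21 (median -1.62, adjusted p = 8.09e-12; adjusted p = 0.116 with an estimated correlation). Both lists kept as a sign of handling were lower too. Immediate early and heat shock genes were lower in 5 of 13 cases, 7 over the list alone (median -0.90, adjusted p = 0.0156, and 0.39 with an estimated correlation). Ribosomal protein genes were lower in 11 of 43 cases, also over the list alone (median -0.53, adjusted p = 0.000745, and 0.39 with an estimated correlation). The largest differences included Irx1 (8.41 ± 0.59) and the complement component Hc (8.29 ± 0.32), higher in MET, and the acute phase protein Saa3 (-9.33 ± 1.12) and Serpinb2 (-8.90 ± 0.25, well above background on 1 of 3 MET arrays), lower in MET. In all 4984 genes (25.7%) differed, 2400 higher and 2584 lower, against 2732 without PD 2, 4649 with slide as a fixed block and 3726 within slide 4. The epithelial and mesenchymal medians were 3.57 and -1.59 with the block and 3.58 and -1.71 within slide 4. Of the 18 lists called, 12 kept the call with the block and 17 within slide 4. Lost with the block were MHC class I, NF-kB and chemokines, hypoxia and glycolysis, luminal epithelium, smooth muscle, and sterol and fatty acid synthesis, and lost within slide 4 was hypoxia and glycolysis.

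Against WT, 8820 genes (45.4%) differed in PD, 3759 higher and 5061 lower, and 8996 (46.3%) in MET, 3749 higher and 5247 lower. With slide as a random block these counts were 8016 and 8044. Spp1 rose by 11.49 ± 1.14 in PD (n = 2 and 3), and Lyz2 rose by 9.32 ± 0.61 in PD and by 8.48 ± 0.55 in MET (n = 3 and 3). Tgm4 fell by 10.73 ± 0.51 in PD and by 10.36 ± 0.45 in MET, and Pbsn fell by 9.69 ± 0.37 in PD and fell by 9.86 ± 0.33 in MET. Vim rose by 8.35 ± 0.38 in PD and by 5.71 ± 0.34 in MET, whereas Cdh1 fell by 2.99 ± 0.41 in PD and rose by 1.59 ± 0.37 in MET. Kras was 0.17 ± 0.23 in PD (adjusted p = 0.585) and rose by 1.65 ± 0.21 in MET (adjusted p = 0.000175).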

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

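The epithelial, luminal epithelium, fibroblast, smooth muscle, ribosomal protein, hypoxia and glycolysis and MHC class I results were picked by a rule. The medians of 2 tumour groups had opposite signs against WT, at least 1 group passed camera against WT, and the direct comparison passed. In each case the other group did not pass against WT, so its move to the opposite side of WT is not shown. In MET against WT the MHC class I and hypoxia and glycolysis medians (-0.17 and -0.24) lay near the median of all genes (-0.21). The mesenchymal and lung epithelium lists and the interferon genes of WD 1 do not meet that rule and were added after their values were seen. The tests within slide 4, on an unchanged makeup of the other cells, on lesions arising in the lung and on the interferon genes of WD 1 were chosen only after the result was seen.

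Epithelial genes were lower and mesenchymal genes higher in PD than in WD: the epithelial median was -4.58 between the groups (PD -4.15 and WD 0.29 against WT), the luminal epithelium median -4.16 (-3.83 and 0.46) and the fibroblast median 6.46 (5.33 and -1.01). A lower share of epithelial cells with unchanged other cells would raise other cell types alike. Among genes above background on every WD array the fibroblast mean exceeded the macrophage and neutrophil mean by 2.40 ± 0.84 (SE over genes). The macrophage and neutrophil mean was 3.44 ± 0.35. The endothelium (3.1 ± 0.34), red blood cell (2.47 ± 0.92) and smooth muscle (2.41 ± 0.71) means lay closer to it. The lymphocyte (1.73 ± 0.41), seminal vesicle (0.39 ± 0.45) and lung epithelium (-0.24 ± 0.4) means were lower still. The test cannot decide, since its SE covers spread over genes, with an estimated correlation of 0.55 in the fibroblast list, not spread over arrays. Fibroblasts captured with or in place of tumour epithelium remain a candidate source: a second list of 26 fibroblast genes, none on another list, had a median of 2.41 with 17 genes higher (camera p = 1.48e-09; 0.0237 with an estimated correlation), and the log2 sample signal of the collagen Col3a1 was 19.92 in PD against 10.99 in WD, and of Col1a2 19.89 against 10.66. Of the 18 fibroblast genes 14 were above background on every WD array and none is on another list, and laser capture by histology included no sort against fibroblasts. Tumour cells that themselves express these genes, which the difference in histological grade allows, would give the same values and were not tested.

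Lung epithelium genes were higher in MET than in WD, with a list median of 3.16. Slide is argued against as the whole cause, since the median was 3.49 within slide 3 (2 arrays of each group) and 3.14 within slide 4 (1 of each). Lung tissue captured with the metastases, with no sort to remove lung cells, remains a candidate source. A second list of 18 lung genes had a median of 2.29 with 12 genes higher (camera p = 7.17e-12, and 0.00649 with an estimated correlation). The log2 sample signal of Sftpc was 19.83 in MET against 11.45 in WD, and of Sftpa1 19.70 against 8.86. Primary tumours also read above WT for some surfactant genes. Sftpc was 14.00 in PD and 7.33 in WT, Sftpa1 11.31 and 7.39, and Sftpd 12.88 in WD and 6.92 in WT. Sftpb was 6.83 in WD and 6.85 in WT. Of the 20 first-list genes 15 were above background on every WD array, so their detection was not particular to the lung samples. Lesions that arose in the lung and were captured as metastases cannot be told apart from prostate metastases with lung tissue by the prostate secretory list, whose median was -0.17 in MET against PD, because PD had already lost most of that expression. A change of the tumour cells in the lung, the site the design names, was not tested.

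Interferon response genes were higher in WD 1 than in the other WD arrays by 3.21 ± 0.21 (SE over 20 genes). WD 1 also had the lowest array weight (0.212) and lay apart from WD 2 and WD 3 in the means of the MHC class I list (1.83 against -0.32 and -0.02), the lymphocyte list (1.45 against 0.20 and -0.21), the basal epithelium list (1.41 against -0.66 and -0.87) and the lung epithelium list (1.88 against 0.47 and 0.40). Other lists set it apart too, among them fibroblast (0.114 against -1.647 and -1.525) and endothelium (1.153 against 0.163 and -0.24). The MHC class II mean of WD 1 was higher (1.708 against 0.389 and 0.588) and its MAPK output mean lower (1.047 against 2.52 and 2.291). Whether WD 1 held other captured tissue was not tested. Slide 4 cannot be told apart from a difference of WD 1 itself: MET 3, on that slide, lay above MET 1 and MET 2 by 0.30 ± 0.10 (SE over genes) but is 1 array, and PD 1 and PD 2, also on it, had interferon means of 2.76 and 2.91. Immune cells like those in PD would predict an interferon mean in PD at or above that of WD 1. The PD mean lay below it (-1.54 ± 0.25, SE over genes) although the macrophage and lymphocyte means of PD were higher. The test cannot decide, since WD 1 is 1 array. Its SE also covers spread over genes with an estimated correlation of 0.83, not spread over arrays. An interferon response in the animal or region of WD 1 stays open and was not tested.

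The fibroblast median was also 3.42 in MET against WD (MET 1.81 and WD -1.01 against WT), while the second fibroblast list had a median of 0.66 there, with 9 of 26 genes higher and 1 lower (camera p = 0.000122; 0.11 with an estimated correlation). For smooth muscle it was 2.13 in PD against WD (1.60 and -0.76), and for ribosomal proteins 0.63 (0.34 and -0.26). The hypoxia and glycolysis median was -0.85 in MET against WD (-0.24 and 0.89) and -0.92 in MET against PD (-0.24 and 0.78). The call in MET against PD was lost without PD 1 (-0.95, adjusted p = 0.0513), PD 2 (-0.74, adjusted p = 0.0607), WD 1 or any of the 3 WT arrays, and with slide as a fixed block (-1.05, adjusted p = 0.0602). In MET against PD the MHC class I median was -1.45 (-0.17 and 1.72), lost with slide as a fixed block (-1.02, adjusted p = 0.0602), and the ribosomal protein median -0.53 (-0.12 and 0.34), lost in the series matrix values (-0.32, adjusted p = 0.082). With an estimated correlation none of these list differences passed, with adjusted p from 0.0548 for the epithelial list to 0.502 for MHC class I.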

How the results depend on the processing

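The tests within slide 4 were chosen only after the result was seen. Over the alternatives, 145 of 151 counts of changed genes stayed within 1.5 times the reported count, 5 fell below and 1 rose above. Of 5495 list values 5221 kept their call or lack of one, 195 lost a call, 70 gained one and 9 were counted as turned in direction. A turn was counted only where the main or the alternative fit passed, or for the epithelial and mesenchymal lists in the main comparisons. Lists that passed in neither fit could change sign uncounted. Basal epithelium in WD against WT did so, with medians from -0.77 to 0.27 when each array was left out. Of 136 named gene results that passed, 136 kept their direction and 131 their call in the alternatives that gave a value for them, which not every alternative did. Aquantile normalisation between arrays moves no ratio by construction.

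For PD against WD the count was 2690 with the 2 groups alone and 3056 to 6098 when each array was left out. For MET against WD it was 7253 with array weights and 1816 within slide 4, and for MET against PD 2732 to 6424 when each array was left out. The cause of these moves was not tested. The epithelial median in WD against WT was 0.56 with the sample channel alone, 0.29 with the 2 groups alone and 0.47 with array weights, each past the threshold, and 0.17 to 0.40 when each array was left out. The mesenchymal median there was -0.043 with array weights and -0.059 to 0.41 with arrays left out. With an estimated correlation camera lost 96 list calls. No other setting was altered, and list medians do not depend on it, but a higher correlation does not account for every lost call. The estimates were 0.23 for the epithelial and 0.18 for the mesenchymal list, against the preset 0.01. The TGF-beta response list lost its call in PD against WD (adjusted p = 0.0607) with an estimate below the preset (0.000456). There the unadjusted camera p went from 0.000414 to 0.00694. For the prostate secretory list in WD against WT, with an estimate of 0.0112, it went from 0.0012 to 0.0146. The test with an estimated correlation was therefore stricter even where the correlation was near or below the preset. For the epithelial (-4.58) and mesenchymal (4.53) lists in PD against WD the camera adjusted p became 0.0548 each. In MET against WD (-1.04 and 1.46) it became 0.271 and 0.2.

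Within slide 4 the medians turned for MHC class I (-0.10), interferon response (-1.58) and sterol and fatty acid synthesis (0.024) in PD against WD, and for ribosomal proteins (0.22) and sterol and fatty acid synthesis (0.40) in MET against WD. The MAPK output median in PD against WD ran from -0.48 (without WD 1, adjusted p = 0.0251) to 0.18 when each array was left out and was 0.39 within slide 4 (adjusted p = 0.0331), so it passed in both directions, and the neuroendocrine median was 1.14 when both channels had to be well above background on all arrays. The interferon response median in PD against WD was 1.52 without WD 1 (adjusted p = 9.82e-05) and 1.25 with array weights (adjusted p = 0.00294), and WD 1 is the WD array on slide 4. Pten was 0.57 in MET against WT and 0.81 in MET against PD when all its probes were averaged. The cause was not tested.

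The replicate number used as a block gave 7445 changed genes for WD against WT, 4289 for PD against WD, 4088 for MET against WD, 8559 for PD against WT, 8689 for MET against WT and 4429 for MET against PD, and changed 3 of 210 list calls (androgen receptor targets lost and immediate early and heat shock gained in PD against WD, FOXO targets lost in MET against PD) and no named gene call. Correlations of same-number arrays ran from -0.271 to 0.181 (median -0.003, 15 pairs), and those of different-number arrays from -0.236 to 0.322 (median -0.015, 30 pairs). Above 0.1 were 5 of the same-number and 3 of the different-number pairs. Same-number pairs gave 0.107, 0.098 and 0.176 for WT with WD, where every different-number pair was negative, but -0.184, 0.158 and -0.271 for WD with MET. The numbers were not used as pairs, and pairing is not excluded. The 10 splits of 6 arrays are too few for a share under 0.05: as many genes came from 1 split, the real one, in WD against WT (7775, highest other 0), MET against WT (8996, highest other 0) and MET against WD (4284, highest other 5). Between 65.3% and 83.3% of probes were well above background, so a gene well above background on no array of a group has a bound there, and a gene dim on some arrays was tested with those dim signals included.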

Other observations

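No test in this part was chosen only after the result was seen. Chromatin regulators went both ways in WD against WT (n = 3 and 3): Ezh2, a histone methyltransferase, rose by 3.34 ± 0.39 and Dnmt3b, a DNA methyltransferase, fell by 1.86 ± 0.26, and 4 of 30 rose and 8 fell, also adjusted over the list alone (median -0.27, adjusted p = 0.739 in limma camera). Neither the chromatin regulators nor the histone deacetylases passed as lists in any of the 6 comparisons. In PD against WD the inflammatory mediators Il6 and Ptgs2 rose by 7.50 ± 0.79 and 6.67 ± 0.81 and the neuronal enolase Eno2 by 4.34 ± 0.43, while Sox2, a stem cell factor, was at least 51.5-fold lower by the sample channel (n = 2 and 3). In WD the probe was well above background on 2 of 3 arrays for Il6 and 1 of 3 for Ptgs2. The neuroendocrine list had 3 genes higher and 1 lower of 13, the same adjusted over the list alone, with a median of -0.01 and a mean of 0.51 (adjusted p = 0.386). Lipid synthesis genes Scd1, a desaturase, and Fasn, the fatty acid synthase, rose in MET against WD by 5.70 ± 0.31 and 3.04 ± 0.24 (n = 3 and 3) and were higher in MET than in PD by 4.95 ± 0.35 and 3.68 ± 0.27. Lung epithelium genes were higher in the same comparisons (medians 3.16 and 3.40). Whether tumour cells or captured lung cells carried Scd1 and Fasn was not tested. In MET against PD 7 of 23 sterol and fatty acid synthesis genes were higher and 1 lower, also over the list alone (median 0.78, adjusted p = 0.00814; adjusted p = 0.39 with an estimated correlation), a call lost with slide as a fixed block (0.38, adjusted p = 0.139), and in MET against WD the median was -0.16 and the mean 0.07 (adjusted p = 0.768).

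Basal epithelium genes fell in PD against WD in 5 of 14 cases and rose in 1, the same adjusted over the list alone (median -2.53, adjusted p = 0.011; adjusted p = 0.339 with an estimated correlation), and the median was -0.77 without WD 1, -1.43 without PD 1 and -1.23 with array weights. MHC class I genes rose there in 1 of 9 cases, also over the list alone (median 0.99, adjusted p = 0.0291; adjusted p = 0.601 with an estimated correlation), and the call was lost without WD 2 (0.64, adjusted p = 0.111), WD 3 (0.99, adjusted p = 0.0745) or PD 2 (0.80, adjusted p = 0.0832) and with slide as a fixed block (0.51, adjusted p = 0.235). Red blood cell genes rose in 3 of 6 cases, also over the list alone (median 2.02, adjusted p = 0.017; adjusted p = 0.128 with an estimated correlation), with a median of 1.06 without the filter on dim probes. Ribosomal protein genes rose in 6 of 43 cases, 4 over the list alone (median 0.63, adjusted p = 0.000108; adjusted p = 0.293 with an estimated correlation). Of 17 FOXO targets 2 rose and 4 fell, and of 30 oxidative phosphorylation genes 1 rose, none over the list alone (medians -0.32 and 0.06, adjusted p = 0.216 and 0.616). The seminal vesicle list passed no gene in WD against WT (6 genes, median 2.16, adjusted p = 0.137), with a list mean of 5.46 in WD 2 against 0.40 in WD 1 and 0.21 in WD 3. It passed without WD 1 (2.86, adjusted p = 0.0491) or WD 3 (3.07, adjusted p = 0.0407). Genes of the tissues in the reference pool did not pass as lists in WD against WT: reference testis (0 rose and 3 fell of 7, median -0.79, adjusted p = 0.153), reference liver (1 and 2 of 7, -0.07, 0.787) and reference kidney (0 and 3 of 6, -0.74, 0.266). Lymphocyte genes in MET against WD rose in 3 of 20 cases and fell in 1, also over the list alone, with Cd79b at 4.36 ± 0.18 (median 0.02, adjusted p = 0.351).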
